A study of Mus musculus with 72 samples.

How the data were processed

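RNA abundance was measured in bone-marrow-derived macrophages, phagocytes grown here from marrow progenitors of male mice in medium with M-CSF, the growth factor that directs progenitors into this lineage. Per the labels, the cells were differentiated for 6 days and came from the C57BL/6 strain carrying Per2::Luc, a luciferase reporter placed in the Per2 clock gene. The cultures were given a serum shock, a brief exposure to concentrated serum that sets the clocks of cultured cells to a common phase, and were then sampled every 2 h from 16 h to 62 h in 3 replicate time courses. This gives 72 libraries, 1 for each of 24 time points in each course. Nothing in the labels says that the courses came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

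Per the labels' protocols, total RNA was purified on columns, ribosomal RNA was depleted, and libraries were sequenced as read pairs on an Illumina HiSeq. DRAGEN, HTSeq and the GRCm38 (mm10) mouse genome are named in the submitters' processing notes. The versions of these tools, the annotation release, the strand setting of the counting and any read trimming are not given in the sources used here. The values deposited by the authors are whole-number counts per gene for each library, with gene symbols as identifiers and no normalization, as the values themselves show. Each library's table holds 49568 genes and 5 closing lines that name no gene. Those 5 lines were left out of library sizes and tests. Of all reads or read pairs tallied, the line for no annotated feature held 29.84% to 36.61% (median 32.84%), the line for alignments that were not unique held 19.55% to 32.97% (median 27.17%), and the line for ambiguous assignment held 1.23% to 1.76%. No 2 libraries held identical values.

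Counts assigned to genes came to 45309360 to 67839053 per library (median 55040063), and 13115 genes were never counted. Genes were kept by edgeR's filterByExpr with the time point as group, which left 17903 genes tested. The counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit, quasi-likelihood F tests) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The rhythm model held a straight-line term for time and a cosine and a sine of a 24 h period, with no term for the course. Rhythm was tested by both periodic terms together. The amplitude is the distance from the middle of the fitted curve to its peak on the log2 scale, and the peak time is the hour of the fitted maximum after serum shock, modulo 24 h. Drift is the straight-line term, given as the log2 change over the 46 h sampled. In the same framework, time points were compared as 24 levels, the periodic terms were compared between the first cycle (16 to 38 h) and the second cycle (40 to 62 h) and between courses, and periodic terms of 12 h were added. Samples were treated as independent, and correlation between successive times within a course was not modelled.

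The replicate number names a time course, and the labels give no animal, batch or day for it, so the main model has no term for it. The level of 3675 genes differed between courses. A fit with the course as a block was run as an alternative.

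The clock period was estimated in each course as the period that best fitted the rhythmic core clock genes together on log2 CPM (counts scaled to library size, prior count 2), and is given as the mean and SD of 3 courses. A total of 48 gene lists was fixed before the data were examined. Each list was scored in each library by the mean of its members' log2 CPM after centring every gene, and the score was tested with the rhythm model in 72 libraries, adjusted over 48 lists. Rhythmic members were also counted with adjustment over the list alone and tested by Fisher's exact test. As a further test, camera in limma 3.58.1 compared the drift of members with that of other genes, with a preset and with an estimated correlation between members. The lists, designs, most alternatives and the naming rule were chosen before the data were examined.

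The rule names every core clock gene tested. For rhythm it names the 14 largest amplitudes among genes past the threshold with a mean of at least 5 CPM, an unadjusted p under 0.05 in each course fitted alone and a peak within 4 h of the pooled one in each. For drift it names the 12 largest rises and the 12 largest falls with the same sign in each course and at least 5 CPM, and for the cycle difference the 8 smallest p-values with the same direction in each course. Up to 4 members with the smallest adjusted p are named per list and test. For the course difference and the 12 h component it would name up to 5 genes each, and no gene qualified. Predicted genes, Riken clones and pseudogenes were passed over except in the lists. A further 24 genes, those with the smallest p under the spline drift described next among genes called rhythmic in all 3 drift models and alike in each course, were chosen after their values were seen.

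Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 likelihood ratio test, no filter, a filter at a mean of 5 CPM, the course block, each course left out, no drift term, a quadratic drift term, periods of 22 h and 26 h, and other list scores. After the data were seen, a natural spline of time with 3 degrees of freedom replaced the straight line, and 6 libraries that stand apart from a smooth course were left out, alone and together. These were course 1 at 40, 56 and 62 h, course 2 at 22 and 60 h and course 3 at 22 h, whose median absolute residual exceeded 0.176 on the log2 scale. Gene coordinates and overlaps came from GENCODE M21 on GRCm38, which gave positions for 358 of the 362 genes named. It may not be the annotation the authors used. Exons of 118 of them overlap exons of another gene.

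The models were tested on simulated counts made from the means and library sizes of the real data, with 100 changed genes per size. Apart from the change under test the means were flat over time, with no course differences and no libraries that stand apart. Changed genes had a mean of at least 5 CPM, so recovery in the real data may be lower. At a rhythm amplitude of 0.25, 99% of changed genes were recovered, and 100% at 0.5, with 3.9% of calls false. For drift, 97% were recovered at 0.5 and 100% at 1, with 4.8% false. Differences between time points were recovered for 97% of genes at 1 and 100% at 2, with 2.5% false. For the cycle difference 100% were recovered at 0.5 and at 1, with 4.3% false. For the course difference 97% were recovered at 0.5 and 100% at 1, with 5.7% false, and for the 12 h component 99% at 0.25 and 100% at 0.5, with 5.7% false. All of these sizes are on the log2 scale. Of 48 simulated lists, 3 were changed and 3 were recovered for rhythm and for drift, with 0 and 1 other lists called. Tables and plots were made with Python 3.11.15.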

Results

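The data are counts of sequenced RNA fragments per gene in mouse bone-marrow-derived macrophages sampled every 2 h from 16 h to 62 h after serum shock. Each of the 24 time points has 3 libraries, 1 from each of 3 replicate time courses, and no unsynchronised or untreated group was analysed here. Libraries held 45309360 to 67839053 counts assigned to genes, with a median of 55040063, and 17903 genes were tested. At the median depth 1 CPM is about 55 counts, and the genes named below at under 1 CPM rest on fewer.

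The first comparison asks which transcripts oscillated with a 24 h period. The core clock was rhythmic: Per2, a repressor of the clock and the gene that carries the reporter, had the largest amplitude of the listed clock genes at 1.26 ± 0.06 (log2, SE) and peaked at 3.83 ± 0.20 h after serum shock modulo 24 h. Its mean level went from 1.05 ± 0.385 CPM at 16 h to 8.55 ± 1.57 CPM at 26 h (SD, n = 3). Arntl, which encodes the activator BMAL1, peaked far from Per2 at 14.98 ± 0.46 h with an amplitude of 0.51 ± 0.06, and its partner paralog Npas2 peaked at 14.56 ± 0.58 h with an amplitude of 0.45 ± 0.06. Nr1d1, the REV-ERBα repressor of Arntl, peaked at 22.78 ± 0.31 h with an amplitude of 0.57 ± 0.05. Of 19 listed core clock genes 17 were tested, and 10 passed over all genes (12 adjusted over the list alone), with adjusted p from 1.02e-25 for Per2 to 0.0253 for Clock.

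The other repressors peaked between Nr1d1 and the activators. Nr1d2, the paralog of Nr1d1, peaked at 0.90 ± 0.26 h with an amplitude of 0.51 ± 0.03, Per1 peaked at 0.94 ± 0.30 h with 0.50 ± 0.04, and Ciart, a repressor of BMAL1 activity, peaked at 0.95 ± 0.53 h with 0.71 ± 0.10. Cry2, a cryptochrome repressor, peaked at 2.39 ± 0.30 h with an amplitude of 0.55 ± 0.04. Cry1, the late-acting cryptochrome, peaked last of the repressors at 6.40 ± 0.28 h with an amplitude of 0.70 ± 0.05. Clock, the partner of BMAL1, had an amplitude of only 0.09 ± 0.02 and was the single called clock gene that lost the call with a quadratic drift term (adjusted p = 0.0659). The other 9 were called in all 3 drift models (straight line, quadratic, natural spline) and had an unadjusted p under 0.05 in each course. The kinases Csnk1d and Csnk1e, the ubiquitin ligase gene Fbxl21, the repressors Bhlhe40 and Bhlhe41 and the nuclear receptor Rora did not pass, with adjusted p from 0.0675 for Csnk1e to 0.683 for Bhlhe41. With a quadratic drift term Csnk1e (0.00737) and Rora (0.0336) were called, and with the spline neither was (0.603 and 0.919). Per2 lies on chromosome 1 from 91415982 to 91459324, Arntl on chromosome 7 from 113207465 to 113314126, and Cry1 on chromosome 10 from 85131700 to 85185064 (GRCm38). Exons of Nr1d1 overlap those of Thra on the other strand, exons of Arntl those of Gm45355 and exons of Cry2 those of D930015M05Rik, and the strand setting of the counting is not given in the sources used here.

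**Figure D1:**
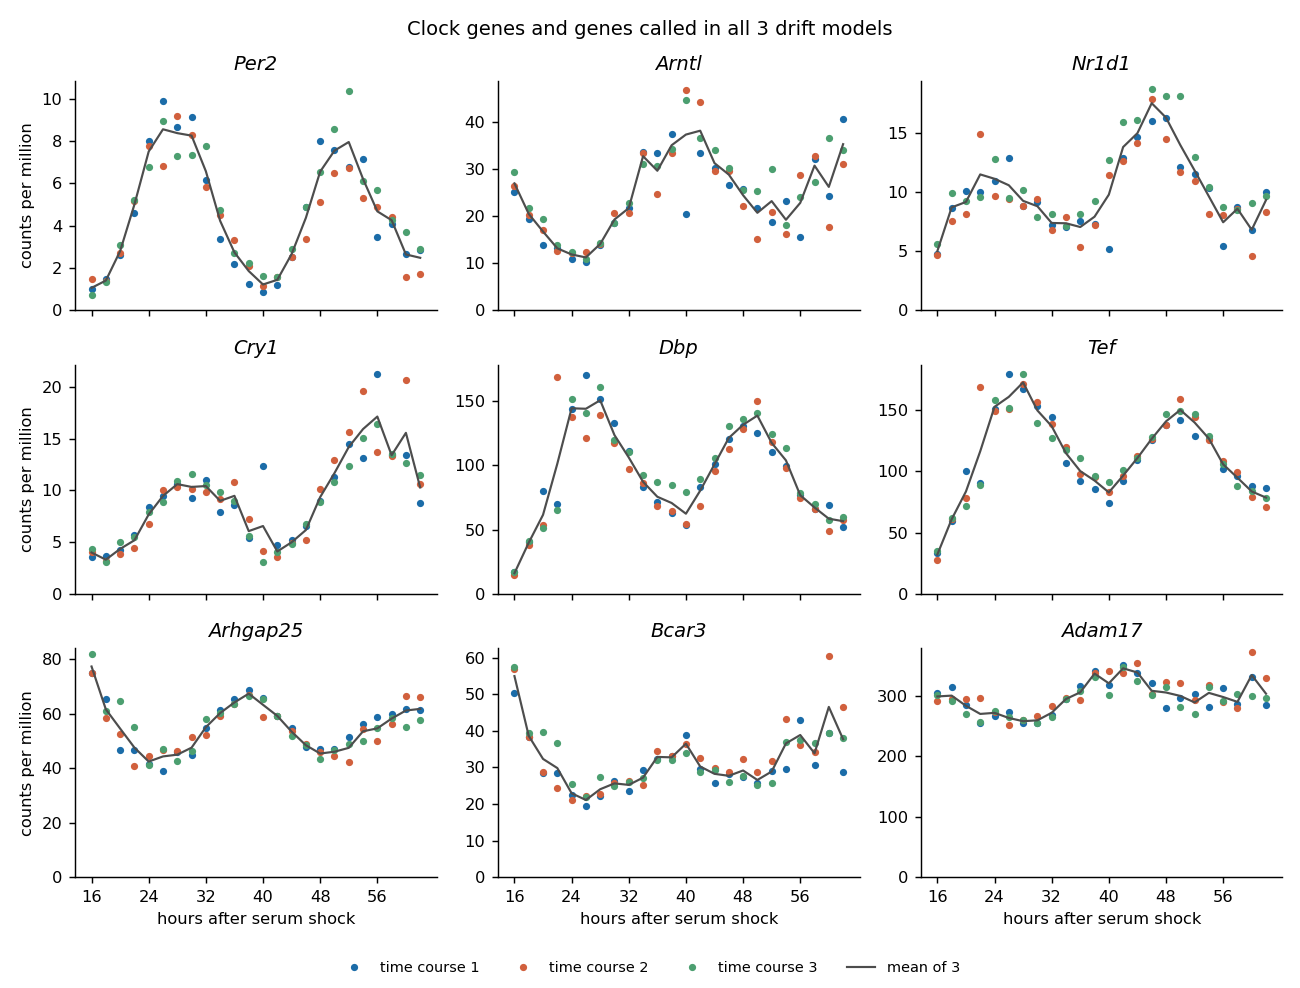
CPM against hours after serum shock for 9 genes, 1 point per library coloured by time course and a line through the mean of 3. Per2 reached 8.55 CPM at 26 h from 1.05 CPM at 16 h, and Arntl was lowest at 26 h with 11.2 CPM.

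Dbp and Tef, members of the PAR bZIP family that the clock drives, peaked at 2.56 ± 0.40 h with an amplitude of 0.74 ± 0.07 and at 3.22 ± 0.37 h with 0.57 ± 0.05. Nfil3, which binds the same DNA motif as a repressor, peaked far from them at 13.12 h with an amplitude of 0.26 (adjusted p = 0.0166). Wee1, a kinase that holds back entry into mitosis, peaked at 7.07 h with an amplitude of 0.46 (adjusted p = 0.000423). In the PAR bZIP and clock output list, 8 of 13 tested members were rhythmic (9 adjusted over the list alone) and 6 were called in all 3 drift models. Ciart belongs to this list as well as to the core clock list. The list score had an amplitude of 0.19 ± 0.02 with adjusted p = 4.30e-09. Exons of Dbp overlap those of Sphk2, which was called with a smaller amplitude of 0.13 ± 0.02 at 2.92 ± 0.77 h.

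Genes outside the clock were called rhythmic as well. Of the 303 genes called in all 3 drift models, clock genes included, 252 differed between the cycles with straight-line drift. The amplitude was lower in the second cycle for 227 of them, so an early change that fades was not told apart from a rhythm. The genes of this paragraph were named after their values were seen, from those called in all 3 drift models and alike in each course. Arhgap25, a Rac-inactivating protein of phagocytes, peaked at 13.80 ± 0.27 h with an amplitude of 0.30 ± 0.02 and adjusted p = 1.24e-19, going from 77.4 ± 3.99 CPM at 16 h to 42.5 ± 1.73 CPM at 24 h. Nlrp3, the sensor of the inflammasome, peaked at 17.21 ± 0.70 h with an amplitude of 0.23 ± 0.04. Adam17, the protease that sheds TNF from the cell surface, peaked at 17.02 ± 0.51 h with 0.12 ± 0.02. Ptpn22, a phosphatase of immune receptor signalling, peaked at 16.26 ± 0.52 h with 0.26 ± 0.03, and Slc15a3, a histidine and peptide transporter of endolysosomes, peaked at 14.73 ± 0.57 h with 0.28 ± 0.04. Slc7a8, an amino acid transporter, had the largest amplitude of these at 0.54 ± 0.09, and Polr1a, the large subunit of RNA polymerase I, had 0.31 ± 0.06. Elmo2, a partner of DOCK proteins in Rac activation, had an amplitude of 0.25 ± 0.04, and the adaptor gene Bcar3 0.32 ± 0.05. Peaks of all of these lay between 13.80 h and 17.21 h with straight-line drift, and peak times depended on the drift term by more than their SE. With the spline Polr1a peaked at 13.70 h, Nlrp3 at 14.18 h and Bcar3 at 12.61 h, against 3.11 h for Per2 and 14.04 h for Arntl. Of the 303 genes called in all 3 drift models, 103 peaked from 16 to 20 h and 97 from 4 to 8 h with the straight line, and 138 from 12 to 16 h and 96 from 0 to 4 h with the spline. Away from these were Msrb1, which repairs oxidised methionine, at 7.05 ± 0.45 h with 0.36 ± 0.05, Tspan4, a tetraspanin of migrating cells, at 5.61 ± 0.51 h with 0.17 ± 0.02, and the glutathione transferase Gstt2 at 4.27 ± 0.74 h with 0.28 ± 0.05. Sdc4, Hnrnpl, Tmem132a, Arl6ip6, Cdk20, Ptpre, Fam134b, Ccdc85b and Snx18 were also called, with amplitudes from 0.09 for Fam134b to 0.28 for Tmem132a. Exons of Tmem132a overlap those of Slc15a3 on the other strand and both had a spline peak of 13.69 h, so it is uncertain whether these are separate rhythms.

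**Figure D2:**
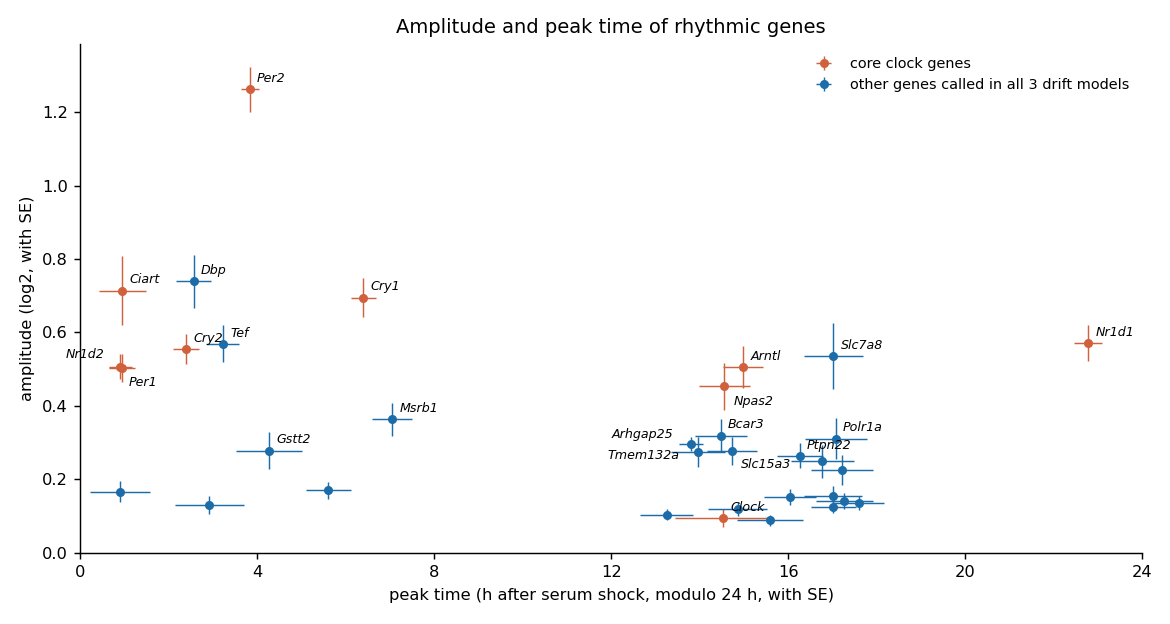
Amplitude (log2) against peak time (hours after serum shock, modulo 24 h) for the 10 rhythmic core clock genes and 24 other genes called in all 3 drift models, with SE bars. Per2 has the largest amplitude at 1.26, and most of the other genes peak between 13 and 18 h.

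In all, 1356 genes (7.6% of those tested) were rhythmic, with a median amplitude of 0.16, and 184 of them passed in each course with peaks within 4 h. Among the 14 genes with the largest amplitudes by the rule, 12 belong to replication or division. These are the histone genes Hist1h2af, Hist1h3b, Hist1h3g, Hist1h2ah, Hist1h3c, Hist1h2bh and Hist1h2ag, with amplitudes from 0.63 to 0.83 and peaks from 7.16 to 7.91 h. With them were the mitotic genes Cdc20, Birc5, Cep55 and Kif14, with amplitudes from 0.64 to 0.68 and peaks from 8.34 to 8.83 h, and Parpbp, a regulator of homologous recombination. Dbp and Cry1 were the other 2. All 12 lost the call when the drift term was a natural spline, with adjusted p from 0.119 for Hist1h2ag to 0.922 for Birc5, and their levels fell over the course. The histone paralogs are near-identical in sequence, and counts of single members are uncertain. In all, 504 genes were called with the spline, 333 of them among the 1356, and 303 in all 3 drift models, while leaving out course 1, 2 or 3 left 291, 233 or 321. Without the 6 libraries that stand apart, 1758 genes were called, 1273 of them among the 1356.

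Rhythms of gene groups were tested with a score per library. In the G2 and M phase list, 24 of 24 members were rhythmic (24 adjusted over the list alone), the score peaked at 8.36 ± 0.71 h with an amplitude of 0.56 ± 0.11 and adjusted p = 0.000424, and 0 members were called in all 3 drift models. Kif20a, Ccna2, Bub1b and Tpx2, which drive spindle and mitotic entry, had amplitudes from 0.46 to 0.63, and with the spline the score had adjusted p = 0.893. Among replication-dependent histones, 10 of 15 were rhythmic (14 adjusted over the list alone), 6 in all 3 drift models, and with the spline the score passed at adjusted p = 0.000354 with a peak that moved from 6.44 h to 2.05 h and an amplitude of 0.24 in place of 0.32. The measured histone score was -0.32 ± 0.08 from 16 h at 28 h, -2.52 ± 0.24 at 40 h and -3.65 ± 0.34 at 62 h (SD, n = 3). A fall without return, of a shape the drift terms miss, was not told apart from a rhythm. Among inflammatory cytokines and chemokines, 5 of 19 were rhythmic (10 adjusted over the list alone), 2 in all 3 drift models, with the score at adjusted p = 0.0168 and an amplitude of 0.23, and 0.00882 with the spline, where the amplitude was 0.12 and the peak moved from 17.38 h to 13.55 h. Measured from 16 h, this score stood at -1.67 ± 0.09 at 28 h and -1.48 ± 0.04 at 40 h (SD, n = 3). It had not returned 24 h after the first sample, so an early fall with slow recovery was not told apart from a rhythm. Tnfaip3, a brake on NF-κB, had an amplitude of 0.24 at 16.82 h, Cd40, a costimulatory receptor, 0.37 at 17.84 h, the neutrophil chemokine Cxcl2 0.55 at 16.44 h and the interferon-induced chemokine Cxcl10 0.53 at 20.17 h. In the glucocorticoid response list, 3 of 11 members were rhythmic (4 adjusted over the list alone), among them Per1 and Klf9, and the score had adjusted p = 0.00104, and 0.00235 with the spline. Per1 is also in the core clock list, and Klf9 and Tsc22d3 are in the PAR bZIP list, so this score is not independent of the clock lists. Cold-inducible RNA binding genes, with Sf3b1 and Cirbp rhythmic among 5 tested (3 adjusted over the list alone), passed with the straight line at adjusted p = 0.0168 and not with the spline at 0.563. Ribosome biogenesis, with 5 of 18 rhythmic (15 adjusted over the list alone), passed with the spline at 0.0466 and not with the straight line at 0.0548. Its measured score stood at -1.04 ± 0.02 from 16 h at 28 h and -0.88 ± 0.38 at 40 h (SD, n = 3), so an early fall was not told apart from a rhythm here either. The core clock score passed in both models (amplitude 0.21 ± 0.02, adjusted p = 6.34e-13, and 8.17e-15 with the spline), as did the PAR bZIP score (7.08e-09 with the spline). No other list of the 48 passed in either model. By Fisher's exact test rhythmic members were enriched in the core clock (adjusted p = 1.14e-06), PAR bZIP (1.16e-05), G2 and M phase (5.04e-26) and histone (3.05e-07) lists, and not in the inflammatory (0.0936), glucocorticoid (0.295) or cold-inducible (0.295) lists. The Fisher test takes the straight-line calls and counts members as independent, so its p-values are too small where members move together.

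The number of genes called depended on the period tested. With straight-line drift, 1356 genes were called at 24 h, 4107 at 20 h, 8309 at 30 h and 11216 at 36 h, against 0 at 12 h and 16 h when these periods stood alone. With the spline, 185 genes were called at 20 h, 504 at 24 h, 640 at 30 h and 611 at 36 h. Core clock genes numbered 10 at 24 h in both, but this was no maximum with the straight line, where 12 were called at 20 h and 22 h, 14 at 30 h and 12 at 36 h.

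**Figure D3:**
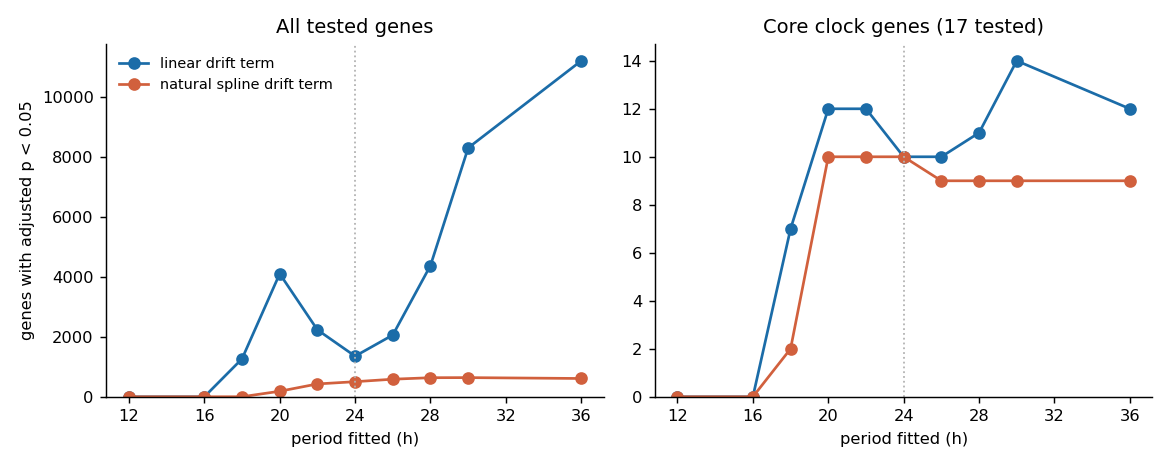
Number of genes with an edgeR adjusted p under 0.05 against the period fitted in hours, for all tested genes and for the 17 tested core clock genes, with a straight-line and with a spline drift term. With the straight line the count over all genes goes from 1356 at 24 h to 11216 at 36 h, and with the spline from 504 to 611.

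The second question was the period of the cultures. Fitted to the 10 rhythmic core clock genes together, it was 24.13 ± 0.15 h (SD, n = 3 courses), with 24.3, 24.0 and 24.1 h in courses 1, 2 and 3. Single genes ranged wider: Per2 gave 24.27 ± 0.15 h, Cry1 25.43 ± 0.45 h, Nr1d1 23.03 ± 0.55 h, Per1 22.43 ± 0.15 h, Ciart 27.27 ± 1.29 h, and the extremes were Clock at 20.30 ± 1.35 h and Arntl at 28.17 ± 0.31 h. With a spline drift term the joint period was 25.07 ± 0.35 h, further from the main estimate than the spread between courses. The genes were chosen for passing a 24 h fit, which can pull the joint estimate toward 24 h by an amount that was not estimated. No test was made of the period.

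The next comparison asks which transcripts had a straight-line trend over the 46 h. Most of those tested did: 6676 genes (37.3%) rose and 5980 (33.4%) fell, 2174 and 2088 of them by at least 2-fold, and the sign was the same in each course for 6561 and 5830. Genes of DNA replication and cell division fell furthest. Hist1h3b, a histone H3 gene, fell from 123 ± 2.68 CPM at 16 h to 0.706 ± 0.193 CPM at 62 h (SD, n = 3), with a fitted change of -10.33 ± 0.30 (log2 over 46 h, SE). A passing trend does not mean a steady change: of the change between the first and the last 3 time points, 41.6% was reached by 38 to 42 h for G2 and M phase, 89.8% for S phase, 99.2% for the TCA cycle, 101.3% for NRF2 and 102.5% for MHC class II. The fitted change can also exceed the measured one, as it does for Hist1h3b, where the 2 means lie closer together than the fitted value.

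The other histone genes with the largest falls were Hist1h2af, Hist1h3c, Hist1h2ah, Hist1h3g, Hist1h2bh and Hist1h2bm, with changes from -10.14 for Hist1h2af to -8.33 for Hist1h2bm. Esco2, which establishes sister chromatid cohesion, changed by a fitted -9.63 ± 0.33, again more than its means, from 30.2 ± 3.62 to 0.175 ± 0.0531 CPM. Pbk, a mitotic kinase, changed by -9.61 ± 0.31, Spc24 and Kntc1, both of the kinetochore, by -8.38 ± 0.27 and -8.37 ± 0.30, and Fam64a, a proliferation-linked gene, by -8.66 ± 0.38. As lists, 24 of 24 G2 and M phase genes fell (24 adjusted over the list alone), with a fitted score change of -6.22 ± 0.26 and adjusted p = 4.95e-33, against a measured -4.10 ± 0.13 (SD, n = 3) from 16 h to 62 h. Top2a, the topoisomerase that untangles chromosomes, went from 423 ± 56.9 to 14.3 ± 1.69 CPM, and Cdk1, the mitotic kinase, from 86.7 ± 11.8 to 9.34 ± 1.56 CPM. All 22 tested S phase genes fell (22 adjusted over the list alone), with a score change of -3.76 ± 0.25: Mcm5, of the replicative helicase, went from 228 ± 19.2 to 4.45 ± 0.531 CPM and Rrm2, of ribonucleotide reductase, from 120 ± 18.6 to 1.98 ± 0.626 CPM. The S phase score had already changed by -2.28 ± 0.12 (SD, n = 3) at 28 h, when the G2 and M phase score stood at 0.41 ± 0.21 above 16 h. All 15 replication-dependent histones fell (15 adjusted over the list alone), by -5.11 ± 0.17 as a fitted score, against a measured -3.65 ± 0.34. With an estimated correlation, camera gave adjusted p = 0.302 for G2 and M phase, 0.326 for S phase and 0.213 for histones, and the 0.213 was the lowest of the 48 lists, so no list held in that test. The preset correlation, which is not measured from the members, gave 3.27e-21, 7.75e-16 and 2.42e-16 for these 3 lists in camera. It gave 1.37e-12 for cholesterol synthesis and 1.82e-06 for glycolysis. MHC class II (0.117), alternative activation (0.256) and LXR targets (0.754) did not pass with it. The summed level of fibroblast and stromal markers was 182 ± 69 CPM at 16 h and 100 ± 41 CPM at 62 h, and ranged from 6.86 CPM in course 2 at 60 h to 553 CPM in course 3 at 22 h.

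Biosynthetic genes fell as well. In the cholesterol synthesis list 23 of 24 genes fell and 1 rose (the same counts adjusted over the list alone), with a score change of -2.35 ± 0.16 and adjusted p = 2.12e-22. Mvk, mevalonate kinase, went from 41.3 ± 2.79 to 7.49 ± 1.02 CPM, the sterol carrier Stard4 from 47.1 ± 2.66 to 8.82 ± 2.83 CPM, and Pmvk and Tm7sf2, further enzymes of the pathway, changed by -1.89 and -2.81. All 11 fatty acid synthesis genes fell (11 adjusted over the list alone), by -2.63 ± 0.16 as a score: the desaturase Fads2 went from 44.5 ± 4.36 to 1.54 ± 0.0861 CPM, and the elongase Elovl5, the acyl-CoA synthetase Acsl3 and the malic enzyme Me1 fell with it. Both lists had adjusted p = 0.326 with an estimated correlation. At 40 h, where course 1 stands apart, their spread between courses was widest among the times tabulated, at SD 0.77 and 0.98.

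Of 19 glycolysis genes 17 fell and 2 rose (the same counts adjusted over the list alone), by -1.21 ± 0.10 as a score: pyruvate kinase Pkm went from 2680 ± 43.1 to 469 ± 95.6 CPM and lactate dehydrogenase Ldha from 1150 ± 88 to 301 ± 44.1 CPM, with Hk1 and Eno1 also falling. All 31 tested nuclear genes of oxidative phosphorylation fell (31 adjusted over the list alone), by -0.56 ± 0.04, among them Uqcrc2, Atp5c1, Atp5a1 and Uqcrc1. Of 22 TCA cycle genes 18 fell and 1 rose, by -0.50 ± 0.05, and of 7 pentose phosphate genes 5 fell, by -0.56 ± 0.04, with transketolase Tkt going from 453 ± 9.41 to 168 ± 1.61 CPM. With an estimated correlation the adjusted p was 0.338 for glycolysis, 0.302 for oxidative phosphorylation and 0.333 for the TCA cycle and the pentose phosphate pathway. Messages made in the mitochondria went the other way: 11 of 11 rose (11 adjusted over the list alone), by 1.00 ± 0.20, with mt-Co1 going from 1670 ± 315 to 2510 ± 411 CPM (adjusted p = 0.733 with an estimated correlation). The mitochondrial ribosomal RNA mt-Rnr2 took 6.07 ± 0.315% of gene counts at 16 h and 10.6 ± 0.441% at 62 h (SD, n = 3).

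NRF2 oxidative stress fell (14 of 17 down and 2 up, -0.77 ± 0.06), where the quinone reductase Nqo1 and the glutathione peroxidase Gpx1 changed by -2.92 and -2.05 and Nfe2l2, the gene of NRF2 itself, rose by 0.81. Interferon response fell (17 of 24 down, -0.88 ± 0.15), where Oas3, an RNA sensor, went from 209 ± 78.9 to 32.8 ± 2.87 CPM and the regulator Irf7 from 197 ± 70.7 to 37.3 ± 7.53 CPM. Actin and SRF targets fell (12 of 15 down and 1 up, -0.68 ± 0.09), with Tagln2, Tpm1, Tpm4 and Flna falling. Adjusted over the list alone, these counts were also 14, 17 and 12. The ATF4 list fell by -0.84 ± 0.19 with 8 of 18 down and 3 up, led by the serine synthesis enzyme Psat1 at -3.52. Cytosolic ribosomal proteins fell by -0.30 ± 0.05 with 26 of 36 down and 3 up, and phagocytic receptors fell by -0.47 ± 0.05 with 9 of 20 down and 6 up, the integrin subunit Itgb2 and the scavenger receptor Scarb1 falling and Cd300a and Fcgr2b rising. Their adjusted p with an estimated correlation was 0.333 for NRF2, 0.733 for interferon, 0.585 for actin, 0.864 for ATF4, 0.733 for ribosomal proteins and 0.766 for phagocytic receptors. Inflammatory cytokines and chemokines fell by -0.43 ± 0.16 with 11 of 19 down and 7 up (the same adjusted over the list alone), but the measured score had gone down further and early, to -1.67 ± 0.09 (SD, n = 3) from 16 h at 28 h and -1.19 ± 0.07 at 62 h. In it the lymphocyte chemokine Ccl5 changed by -3.01 and the costimulatory ligand Cd86 by 3.01, with adjusted p = 0.916 with an estimated correlation.

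**Figure D4:**
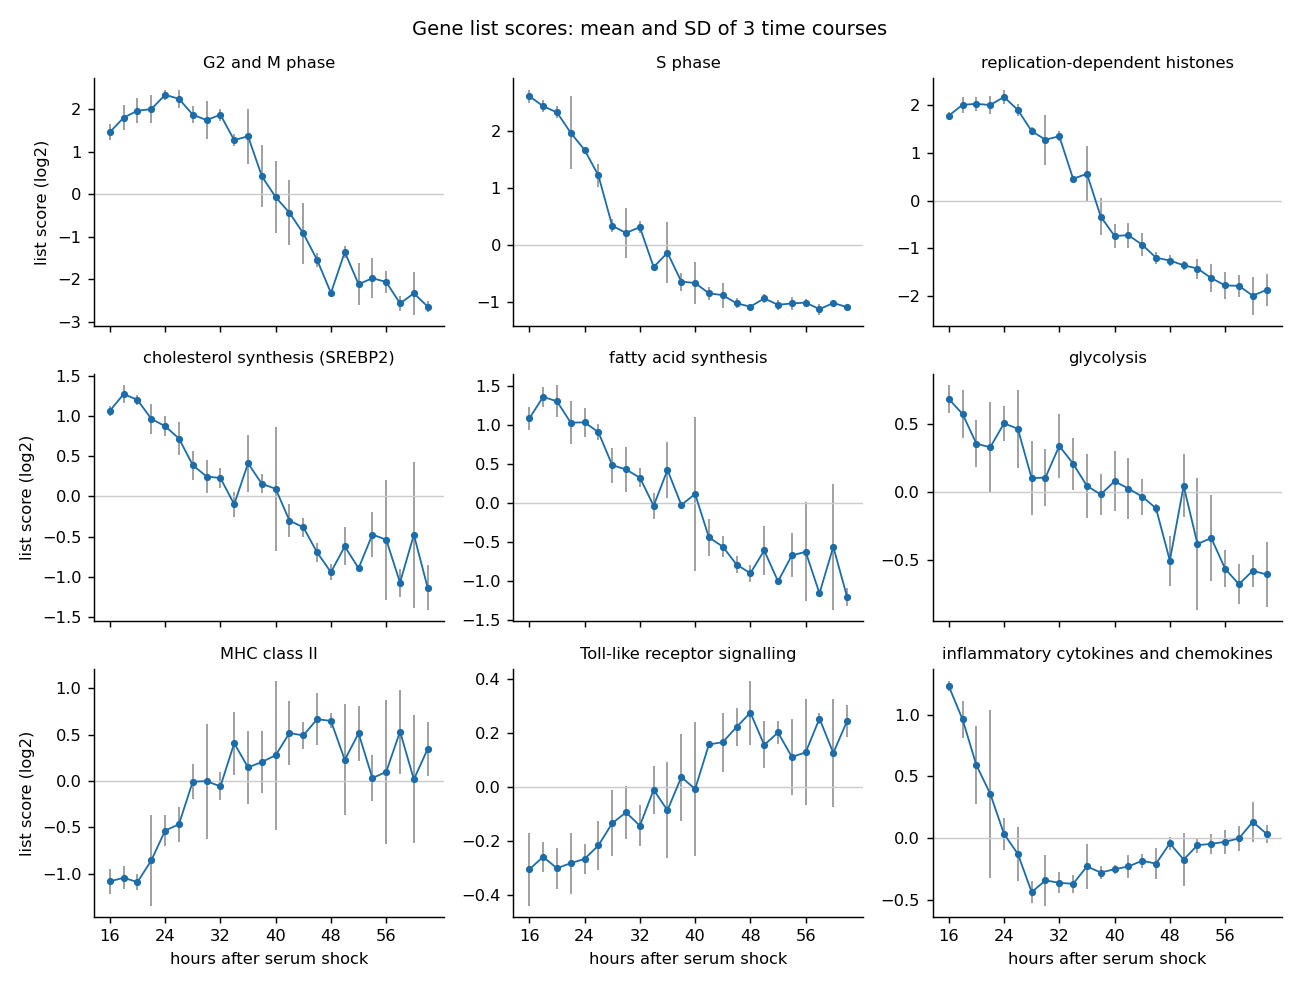
Score of 9 gene lists (mean centred log2 CPM of the members) against hours after serum shock, as the mean of 3 time courses with SD bars. The S phase score falls by 28 h, the G2 and M phase score later, and the MHC class II score rises.

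Of the 12 genes named for the largest rises, Adgre4, an adhesion receptor, changed by 5.21 ± 0.47, from 0.257 ± 0.162 to 13.1 ± 5.51 CPM, Stab2, a scavenger receptor, by 4.63 ± 0.24, from 2.12 ± 0.206 to 44.2 ± 12.7 CPM, and Ms4a4a, a membrane protein of alternatively activated macrophages, by 3.98 ± 0.28, from 2.6 ± 0.263 to 53.1 ± 0.442 CPM. Clec10a, a galactose-binding lectin, went from 26.2 ± 2.69 to 227 ± 119 CPM. Of lipid handling genes, Angptl4, an inhibitor of lipoprotein lipase, changed by 4.88 ± 0.30 and Mgll, a lipase that releases free fatty acids, by 4.86 ± 0.40. Adam22, Gprc5c, Cyp4f18, Sorl1, Thbs1 (thrombospondin) and Ighm (the IgM heavy chain) were the others, with changes from 3.40 for Thbs1 to 4.74 for Adam22.

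Of the immune lists, MHC class II changed by 1.40 ± 0.21 with 5 of 7 genes rising and 1 falling (the same adjusted over the list alone): H2-Aa went from 1.85 ± 0.506 to 9.59 ± 0.334 CPM, H2-Eb1 from 1.86 ± 0.588 to 8.42 ± 0.552 CPM, and the invariant chain Cd74 from 8.68 ± 0.936 to 22.8 ± 1.65 CPM, all low levels. Toll-like receptor signalling rose by 0.65 ± 0.05 with 15 of 20 up and 3 down (16 and 3 adjusted over the list alone), led by Tlr2, the receptor of bacterial lipoproteins, from 63.7 ± 2.8 to 165 ± 21.1 CPM, with Ticam2, Unc93b1 and Tlr5. Alternative activation rose by 0.56 ± 0.11 with 9 of 15 up and 2 down, and Mrc1, the mannose receptor, fell against it from 3070 ± 79.3 to 1280 ± 126 CPM, while Tgfb1 and Mgl2 rose. Immediate early genes rose by 0.78 ± 0.06 with 11 of 21 up and 5 down, Nr4a1, Egr1 and Fosb among them at means under 7 CPM. LXR targets rose by 0.62 ± 0.07 with 5 of 12 up and 4 down, the phospholipid transfer protein Pltp going from 351 ± 44.3 to 2080 ± 217 CPM and lipoprotein lipase Lpl from 210 ± 5.86 down to 51.9 ± 11.9 CPM. Fatty acid oxidation (0.46 ± 0.06, 9 of 16 up and 4 down), lysosome (0.27 ± 0.05, 13 of 26 up and 6 down), and mRNA decay (0.25 ± 0.02, 14 of 24 up and 2 down) rose too. So did nuclear-retained RNA with Malat1 and Neat1 (0.64 ± 0.09, 4 of 7 up and 1 down), macrophage identity (0.14 ± 0.05, 8 of 16 up and 5 down, Cebpa and Mpeg1 rising and Itgam falling) and autophagy (0.14 ± 0.06, 8 of 20 up and 4 down). With an estimated correlation the adjusted p was 0.741 for MHC class II, 0.341 for Toll-like receptor signalling and for immediate early genes, 0.585 for alternative activation, 0.916 for LXR targets, 0.767 for fatty acid oxidation, 0.733 for lysosome, 0.484 for mRNA decay, 0.604 for nuclear-retained RNA, 0.893 for macrophage identity and 0.864 for autophagy. Heat shock, the unfolded protein response, translation initiation, mitochondrial dynamics and ribosome biogenesis did not pass for a straight-line trend, with fitted changes from -0.20 to 0.03. They were not flat: from 16 h to 28 h the measured score moved by -1.04 ± 0.02 for ribosome biogenesis, -0.54 ± 0.05 for heat shock, -0.53 ± 0.04 for the unfolded protein response and -0.30 ± 0.04 for translation initiation, and at 62 h ribosome biogenesis stood at -0.78 ± 0.14. Measured changes at 62 h also differed from the fitted ones for autophagy (0.39 ± 0.05, after 0.58 ± 0.03 at 28 h), alternative activation (0.27 ± 0.20) and immediate early genes (0.46 ± 0.12).

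**Figure D5:**
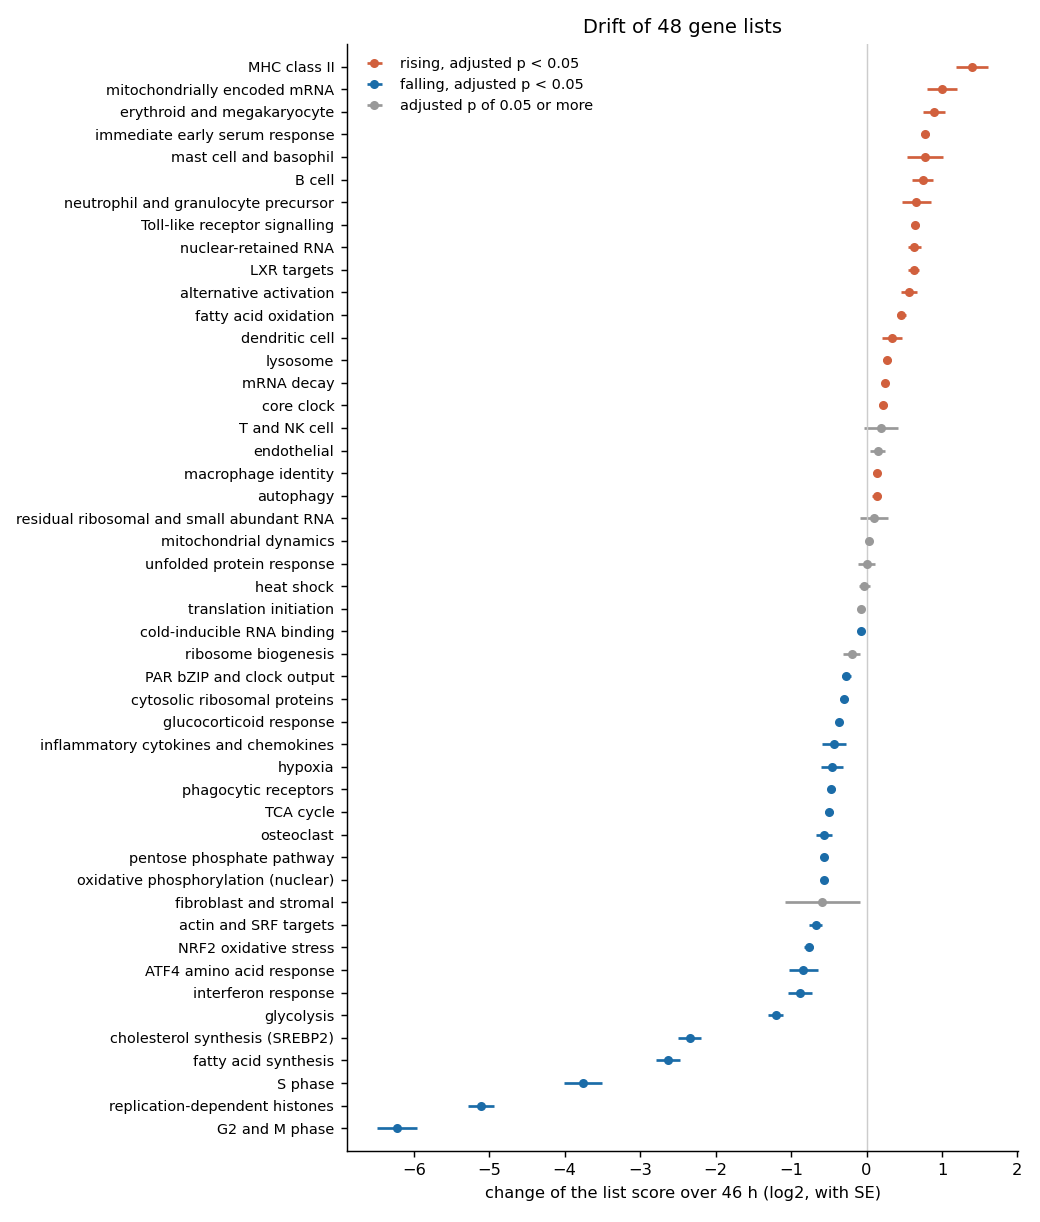
Fitted straight-line change of each of 48 list scores over 46 h (log2, with SE bars), coloured by direction where the adjusted p is under 0.05. The G2 and M phase list lies lowest at a fitted -6.22, where the measured change is -4.10, and MHC class II highest at 1.40, and 18 lists rose while 21 fell.

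Markers of other cell types were measured beside these groups. The mean of the stromal markers did not pass for drift (-0.58 ± 0.49). Among them Col1a2 had a mean of 54.8 CPM and a highest library of 178 CPM, and Col1a1 fell by 1.35. The endothelial list did not pass (0.15 ± 0.10), and Vwf had a mean of 119.8 CPM. Sums over osteoclast markers (596 CPM) and mast cell markers (34.2 CPM) were highest in course 2 at 60 h, where the Kit gene reached 32.2 CPM, and the sum over endothelial markers (338 CPM) was highest in course 1 at 40 h. These are 2 of the 6 libraries that stand apart. Granulocyte genes were low except Csf3r, a cytokine receptor also found on macrophages, which went from 17.2 ± 1.15 to 90.3 ± 10.4 CPM, and of B cell markers Ighm alone exceeded 5 CPM in any library. The list scores for granulocyte, dendritic, B cell, mast cell and erythroid markers rose and that of osteoclast markers fell (-0.56 ± 0.11), with adjusted p of 0.688 or more with an estimated correlation, and T and NK cell markers did not pass. Sums of CPM, which follow the most abundant markers, went the other way for dendritic markers (373 ± 20 to 135 ± 13.2 CPM) and osteoclast markers (164 ± 37.2 to 283 ± 84.7 CPM).

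Compared as 24 levels with no shape assumed, time points differed for 12261 genes (68.5%). Per2 (adjusted p = 8.55e-21), Dbp (1.96e-19) and Rrm2 (1.85e-34) were among them.

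The next comparison asks whether rhythms damped or grew between the cycles. The periodic terms differed between the cycles for 10598 genes, with a lower amplitude in the second cycle for 6511 and a higher one for 4087. This split depended on the fit: the amplitude was lower for 8924 of 10387 with no drift term, 6762 of 8627 without course 1 and 5058 of 9216 without course 3. The 8 genes named for the smallest p-values were all highest at 16 or 18 h: Ptma, an acidic chromatin protein, went from an amplitude of 0.44 to 0.30, and Pcna, the replication clamp, from 0.79 to 0.49. Tfdp1, the partner of E2F, went from 0.57 to 0.31, Dtymk, a thymidylate kinase, from 0.68 to 0.40, the coactivator Trip4 from 0.63 to 0.37, the chaperone Hsp90aa1 from 0.65 to 0.45, and the RNA processing factors Cstf2 and Srsf2 from 0.60 to 0.42 and from 0.54 to 0.38. Each was lower in all 3 courses, but the naming rule admits only genes with the same direction in each course. Of the core clock genes called rhythmic, 8 differed and 4 of these were lower in the second cycle: Arntl went from 0.77 to 0.42, Ciart from 1.07 to 0.49, Cry2 from 0.70 to 0.53 and Nr1d2 from 0.62 to 0.49. With the spline the direction turned for Ciart (0.15, second minus first cycle) and Cry2 (0.62), and no core clock gene was called for the cycle difference, so neither damping nor growth is established for any of them. Nr1d1 went up from 0.47 to 0.74, and Per2 was not shown to differ (1.36 and 1.14, adjusted p = 0.0981). With a spline drift term 8 genes were called in place of 10598 (Camk1, Kif3a, Lysmd4, Nadk, Ogg1, Pmvk, Ptma and Slc4a7, named after their values were seen).

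Rhythms were then compared between the 3 courses. edgeR called 0 genes, with 322 at an unadjusted p under 0.05, and DESeq2 also called 0, with 402 unadjusted. No clock gene was shown to differ between courses, and Per2 peaked at 3.83 h with an SD of 0.35 h over the courses. A 12 h component was likewise called by edgeR for 0 genes, with 536 at an unadjusted p under 0.05, and by DESeq2 for 1 gene, with 610 unadjusted. The simulated data recovered 97% of course differences of 0.5 and 99% of 12 h components of 0.25, both on the log2 scale. Those data held no drift, no other course differences and no libraries that stand apart, and the changed genes had at least 5 CPM. Recovery in the real data may be lower, so the counts of 0 do not show that such differences are absent.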

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

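The spline drift and the comparison with shuffled assignments were chosen after the results were seen, and the cycle difference and the quadratic drift before. The cycle difference is given for a closer look because the periodic terms of 10598 genes differed between the first and the second cycle. Among the 8 genes with the smallest p-values the amplitude changed, second minus first cycle, by -0.13 for Ptma, -0.25 for Tfdp1, -0.29 for Pcna, -0.28 for Dtymk, -0.26 for Trip4, -0.20 for Hsp90aa1, -0.19 for Cstf2 and -0.16 for Srsf2. Among core clock genes it changed by -0.35 for Arntl, -0.58 for Ciart, -0.17 for Cry2 and -0.14 for Nr1d2, and by 0.26 for Nr1d1, 0.08 for Cry1, 0.04 for Per1 and 0.03 for Clock. The test takes amplitude and peak time together, so it can pass with little change in amplitude.

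A gradual change that is not a straight line could be fitted as a rhythm or as a difference between cycles. With a natural spline as the drift term, 75.4% of the 1356 rhythmic genes lost the call, the division genes among them, and 8 genes were called for the cycle difference. In contrast, 9 of the 10 rhythmic core clock genes, Per2, Cry1, Ciart, Nr1d1, Cry2, Nr1d2, Arntl, Per1 and Npas2, were called in all 3 drift models. A drift of the 3 shapes fitted does not account for these calls, but a sharper early change than those shapes allow is not excluded. With the spline 9 core clock genes were also called at each of 26, 28, 30 and 36 h, so the calls are not specific to 24 h. The spline may also absorb part of a true rhythm or of its damping, so these values do not settle the share of genes concerned. Sampling of cultures without serum shock at the same hours, or a longer series, would separate the possibilities.

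The real assignment of libraries to times, cycles or courses was compared with shuffled ones, 40 in all with the real one included. For rhythmic genes the real assignment gave 1356 against a highest other of 0, and for core clock genes 10 against 0, with 1 of 40 as large in each. For rising genes it gave 6676 against 0, for falling genes 5980 against 0, for time points 12261 against 502 and for the cycle difference 10598 against 3483, with 1 of 40 as large in each. Shuffling breaks the order of the times, so any smooth change over time could exceed the shuffled counts. These 6 results therefore show that levels followed time. They cannot tell a 24 h rhythm, a straight line or a cycle difference from other gradual change. For the course difference and the 12 h component the real value was 0 and the highest other 0, and 40 of 40 is the only outcome a count of 0 can give, so nothing about chance follows.

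The line for no annotated feature held a median of 32.84% of all reads or read pairs tallied per library. Whether they lay outside genes, in introns or on the other strand of a gene was not examined. These reads were not analysed here.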

How the results depend on the processing

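The spline drift, the omission of the 6 libraries that stand apart and their combinations were chosen after the data were seen, and the cause of the changes below was not tested. The number of rhythmic genes, 1356, was 233 to 321 with 1 course left out, 3871 with no drift term, 2104 with a quadratic term, 2235 at 22 h, 2062 at 26 h, 504 with the spline, 752 with the spline and the block and 664 with the spline and without the 6 libraries. The cycle difference went from 10598 genes to 4404 with the quadratic term, 8 with the spline, 8 with the spline and the block, and 0 in edgeR with the spline and without the 6 libraries, where no unadjusted or DESeq2 count was made. Rising genes went from 6676 to 4148 at a mean of at least 5 CPM, which tests fewer genes. The course difference went from 0 to 325 genes with no filter, and the 12 h component from 0 to 16 with no filter, 1 in DESeq2 and 1 without the 6 libraries, with 8659 genes not fitted for 12 h without a filter. Rhythmic lists went from 7 to 4 to 5 with 1 course left out and to 12 without the 6 libraries. The clock period was 25.07 h with the spline.

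With the replicate block, 1618 genes were rhythmic, 10 of them core clock genes, 6797 rose, 6042 fell, 13053 differed between time points and 11082 between cycles, 0 had a 12 h component (598 unadjusted in edgeR, and 1 adjusted in DESeq2 without the block), 8 lists were rhythmic and 39 drifted, and the clock period was 24.2 h. No count moved by over 1.5 times. Among named genes and lists the block added 13 rhythm calls (Ifit2, Fcgr2b, Ctsd, Neu1, Atg12, Pdha1, Arl4c, Scd1, Srsf5, Tpm3, Dnajc3, Atp6v0d2 and Ctsk) and the rhythm of the immediate early list, and it ended no call. Deviations from the time point means had a mean correlation of 0.11 within a course, with 53.7% of pairs above 0.1, against -0.05 between courses, and 64 of 72 libraries correlated best with their own course, which is a hint from the data and not the design. Centring on the 3 libraries of each time ties the value between courses to that within them, so the -0.05 is no separate evidence. Genes near the filter hold few counts, and what depth limits was not tested.

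Without a drift term these rhythms peaked more than 6 h from where they did with it: amplitudes were 1.01 for Hist1h2af, 1.11 for Hist1h3b, 1.08 for Hist1h3g, 1.07 for Hist1h2ah, 1.06 for Hist1h3c, 1.04 for Hist1h2bh, 1.01 for Hist1h2ag, 0.98 for Hist1h2ab, 0.85 for Hist1h2ae, 0.42 for Cep55, 0.44 for Parpbp, 0.64 for Birc5, 0.62 for Kif14, 0.36 for Kif20a, 0.59 for Ccna2, 0.48 for Bub1b, 0.48 for Tpx2, 0.31 for Wee1, 0.088 for Tlr5, 0.044 for Pfkfb3, 0.19 for Tkt, 0.033 for Idh3b, 0.04 for Uqcrc2, 0.069 for Atp5c1, 0.082 for Hif1a, 0.16 for Rpl15 and 0.015 for Rpl3. Of these only Rpl15 passed there. With the spline and without the 6 libraries the peak of Birc5 also moved by more than 6 h, with an amplitude of 0.059.

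The amplitude change between cycles turned sign for several clock genes. With 1 course left out it ranged from -0.091 to 0.477 for Bhlhe41, -0.022 to 0.059 for Clock, -0.003 to 0.06 for Csnk1d, -0.138 to 0.007 for Csnk1e and -0.017 to 0.13 for Per1. Without a drift term it was -0.093 for Csnk1d and -0.027 for Per1, and with the quadratic term 0.00 for Csnk1e and 0.14 for Rora. With the spline it was 0.15 for Ciart, 0.62 for Cry2, -0.11 for Per1 and 0.13 for Rora, and with the block added 0.14, 0.62, -0.11 and 0.13 for Ciart, Cry2, Per1 and Rora. Without the 6 libraries it was -0.10 for Bhlhe41 and -0.054 for Clock, and with the spline too 0.34 for Ciart, 0.58 for Cry2, -0.008 for Csnk1d, -0.142 for Fbxl21, -0.045 for Per1 and 0.037 for Rora. The drift of cold-inducible RNA binding genes was 0.10 by the median of members and 0.31 with members scaled to unit SD. Of 206 gene drifts, 206 stayed on the same side of the threshold with DESeq2 size factors and 206 with the block. No called drift changed direction in either, and sizes were not compared.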

Other observations

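The tests weighed in this part were chosen after the results were seen. Ighm, which encodes the IgM heavy chain, rose by 3.69 ± 0.31 over 46 h, from 7.54 ± 1.43 to 84.5 ± 22.5 CPM. RNA of B cells could give such a rise, but the other 6 tested B cell markers had a median drift of 0.36 with an SE of 0.49. Over all libraries Ighm had 193107 counts against 1455 for Cd79a, 151 for Ighd and 0 for Igkc, the kappa light chain. A transcript made by the macrophages from this locus remains possible, and reads over its exons would be needed to tell.

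Genes called in all 3 drift models formed 148 pairs with a tested locus overlapping them on the other strand. A pair was listed from each side where both were called. In 64 pairs the gene was coding and the partner non-coding. Over all 148 pairs, whether the gene was coding or not, 16 had a non-coding partner rhythmic with spline drift. Gm45355 with Arntl, D930015M05Rik with Cry2 and Gm42836 with Bcar3 were among them. By spline peaks 16 of these 16 partners peaked within 3 h of the gene, with a median difference of 0.54 h and a largest of 2.19 h. By straight-line peaks Ciart (0.95 h) and C920021L13Rik (4.91 h) and Morc2a (18.17 h) and Tug1 (13.96 h) lay further apart. Tug1 (85.16 CPM) was higher than Morc2a (35.07 CPM), and C920021L13Rik (28.3 CPM) higher than Ciart (1.502 CPM). C920021L13Rik was not higher than BC028528 (29.1 CPM, 5.84 h), which it also overlaps. The count of a gene may leave out reads of its introns, so these levels do not exclude reads of the other strand. In all of these pairs reads of 1 strand may have been counted at the locus on the other, and true antisense transcription could give the same values. The strand setting of the counting would decide between these.

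The first principal component held 40.1% of the variance and had a Spearman correlation of 0.94 with time.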
